A study of Gallus gallus with 20 samples.

How the data were processed

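Liver RNA of broiler chickens was measured on a spotted oligonucleotide array with 2 colours. Each of the 20 arrays held the RNA of 1 control bird and 1 bird that had been caught, crated, transported and slaughtered (CTS), one labelled with Cy3 and the other with Cy5. The arrays formed 10 bird pairs, each hybridised on 2 arrays with the dyes exchanged, so that 10 control and 10 CTS birds were measured. Both arrays of a pair carried the same extracts and were treated as technical repeats. A pair joins birds only by their shared hybridisation, and the labels give no kinship or other tie between them. In the study 24 birds had been selected, and only those of the 10 pairs were on arrays here. The room of each bird is not given here, and the pairs were taken as independent. Total RNA was extracted with Trizol followed by a column kit, per the labels' protocols.

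Each spot's intensity and local background were given by GenePix Pro 6.0.1.27 from scans at 635 nm (Cy5) and 532 nm (Cy3), per the file headers, which record no normalization. The deposited files also gave the percent of each spot's pixels brighter than the local background by more than 2 SD, and a quality flag. An array had 21888 spots in 9 blocks of 2432. Of these, 20460 were chicken oligos with 1 spot each, 1181 were blank, 218 carried 1 repeated control oligo and 18 were position markers. Spots named for GAPDH (4), β-actin (3) and the insulin receptor (4) made up the rest. The log2 ratios in the table of processed values deposited by the authors ran as Cy5 over Cy3 on every array, by comparison with the scanner intensities of bright spots (Pearson r between 0.944 and 0.997 and slopes between 0.917 and 1.11, across spots within an array). The method behind their centring is not given in the sources used here, and 2.87% to 13.0% of values per array were missing. The column medians with CTS in Cy5 were 0.01 (pair 1), 0.04 (pair 2), 0.02 (pair 3), 0.04 (pair 4), 0.01 (pair 5), 0.03 (pair 7), 0.04 (pair 8), 0.01 (pair 9), 0.01 (pair 10) and 0.01 (pair 12). With CTS in Cy3 they were 0.01, 0.00, 0.01, 0.03, 0.02, 0.01, 0.02, 0.03, 0.03 and 0.04 in the same order of pairs. That table served only as an alternative.

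The median pixel intensity of each spot was corrected for local background by normexp with an offset of 50, fitted on all spots. Log2 ratios were normalised within each array by loess (span 0.3), with weight 0 for spots other than chicken oligos. The median was chosen over the mean pixel intensity before any test, because the means of blank spots exceeded their medians: the mean of blank spots in Cy5 lay 28.5 units above background in the median array and their median lay 4 units above it. Ratios were turned to CTS over control and averaged over the 2 arrays of a pair, in which a dye bias of equal size on both arrays cancels. The 10 averages were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and oligos with a Benjamini-Hochberg adjusted p under 0.05 were called. Dye effects were fitted on all 20 arrays with coefficients for CTS and dye and the pair as a random block. Ratios of the repeated gene spots were averaged per pair and tested by an exact sign-flip permutation test over the 10 pairs, two-sided, with Benjamini-Hochberg adjustment over the 3 genes. The smallest p this test can give is 0.00195. A spot was counted as detected where at least 50% of its pixels exceeded the background by 2 SD.

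The pairing was checked on the deviations of each array from the mean of its dye orientation. Over the brightest 25% of oligos the 2 arrays of a pair correlated at r between 0.31 and 0.78, and each of the 10 arrays with CTS in Cy5 correlated best with its own dye-swapped partner. Over all oligos, most of them dim, r lay between 0.02 and 0.42.

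The method was tested on simulated arrays with the dye effects and spreads of the 20460 oligos and with 200 changed oligos. For CTS against control, 22 of 50 oligos changed 1.2-fold were called in the right direction, as were 49 of 50 at 1.5-fold, 50 of 50 at 2-fold and 50 of 50 at 3-fold. Another 8 oligos without a simulated change were called. The simulated errors were independent between oligos and had the same spread on every array. On the real arrays the SD of log ratios ran from 0.13 to 0.54, and deviations were shared between oligos. The simulated counts may therefore not hold for the real arrays. These sizes are those of the ratio after background correction, which for a dim spot lies closer to 1 than the ratio of its transcripts.

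The arrays were scanned on 2 days, 12 on scan day 1 and 8 on scan day 2. CTS was in Cy5 on 7 of the former and 3 of the latter, and 6 of the 10 pairs had 1 array on each day. Each array held both conditions, so scan day was tested within days and as a covariate. The median oligo lay between 6 and 91 intensity units above background in Cy5 and between 10 and 151 units in Cy3. The main tests of CTS against control count 10 bird pairs, because the 2 arrays of a pair repeat the same extracts. The spread of the pair averages holds both differences between birds and noise of the arrays.

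The chicken oligos carry only probe IDs, and none of these IDs matched the gene table used here. Gene names are therefore not used for them, the gene lists fixed before the data were examined were not tested, and the rule for named genes could not be applied because it asked for a gene symbol. In its place at most 2 IDs per direction are given, those with the largest ratio among called oligos with the same sign in at least 9 of 10 pairs. GAPDH, β-actin and the insulin receptor are reported because their spots carry gene names. Alternatives covered background correction, normalisation, filters, the source of values, single dye orientations, the model, the threshold, scan day and each pair left out.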

Results

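Livers of female broilers, fast-growing meat chickens, were compared between 10 control birds and 10 birds taken through commercial catching, crating, transport and slaughter (CTS) at 49 days of age. The CTS birds had been without food for 8 h and the procedure lasted 3.25 h. Control birds were killed by neck dislocation just before a meal was due. The comparison asked how liver transcript levels differ after these combined stressors, and food withdrawal, handling, transport and the way of killing all differ together between the conditions. Each CTS bird was paired with 1 control bird on 2 arrays with exchanged dyes. The share of oligos detected ranged from 9.47% to 48.1% per array in the CTS channel and from 12.0% to 41.5% in the control channel.

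Transcript levels differed between CTS and control livers in both directions, mostly by small factors in the array ratios. Of 20460 oligos, 357 were higher and 419 were lower in CTS (limma, adjusted p under 0.05, n = 10 pairs). The median change was 1.25-fold for oligos that rose and 1.26-fold for those that fell. A change of at least 1.5-fold was seen for 48 oligos that rose and 52 that fell, and one of at least 2-fold for 6 and 8. Of the 776 changed oligos, 466 had the same sign in all 10 pairs, which was 60.1% of them. Over all oligos that share was 2.91%, against 0.195% by chance. The 60.1% follows in part from the selection, because the calls rest on these same 10 ratios.

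RIGG07310 rose in CTS, at a mean log2 ratio of 1.43 ± 0.55 (SD, n = 10 pairs), or 2.69-fold. It was higher in CTS in 10 of 10 pairs, from 0.26 to 2.30 on the log2 scale (limma adjusted p = 2.77e-05). RIGG04084 was at 1.31 ± 1.34 (SD, n = 10) and 2.49-fold (limma adjusted p = 0.0402). Its pairs ran from -1.08 in pair 8 to 3.15 in pair 12. It was detected on 15 of 20 arrays in CTS and on 9 of 20 in control, and its call was lost in 13 of 31 alternatives, with a limma adjusted p from 0.00131 to 0.177 over all of them. With 1 pair left out, the RIGG04084 call held only without pair 1 or pair 8, and the limma adjusted p ran from 0.00653 to 0.103. RIGG06344 fell in CTS, at -1.45 ± 0.41 (SD, n = 10) or 2.74-fold lower in CTS, with all pairs between -1.99 and -0.88 (limma adjusted p = 3.93e-06). RIGG06395 was at -1.41 ± 0.68 (SD, n = 10) or 2.66-fold lower, between -2.79 and -0.18 (limma adjusted p = 0.000203). RIGG06344 was detected in both conditions on 20 of 20 arrays, RIGG06395 on 16 in CTS and 20 in control, and RIGG07310 on 16 in CTS and 12 in control. With plain background subtraction the log2 ratio of RIGG07310 was 1.91. What RIGG07310, RIGG04084, RIGG06344 and RIGG06395 encode is not given here.

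GAPDH, an enzyme of glycolysis often used as a reference transcript, was lower in CTS livers. Its log2 ratio was -0.35 ± 0.26 (SD, n = 10 pairs), or 1.28-fold lower, and it was below 0 in 9 of 10 pairs (exact sign-flip permutation test, p = 0.00586, adjusted p = 0.0176). The 4 GAPDH spots gave means between -0.36 and -0.35. β-actin, a protein of the cytoskeleton, was also lower in 9 of 10 pairs, at -0.21 ± 0.26 (SD, n = 10) or 1.15-fold lower (exact permutation p = 0.0273, adjusted p = 0.0410). The β-actin ratio was lowest in pair 1, at -0.76, and without that pair its mean was -0.14 with an adjusted p of 0.0820 in the exact permutation test. The β-actin call was lost without any 1 of the pairs except pair 12, with adjusted p between 0.0117 and 0.0820 in the exact permutation tests with 1 pair left out. GAPDH and β-actin kept their direction in all 22 alternatives run for them, and the call was lost in 2 for GAPDH and in 12 for β-actin. The insulin receptor, the cell-surface receptor of insulin, was detected in 1.25% of 80 spot readings in each condition and so was not well above background. Its log2 ratio was -0.03 ± 0.15 (SD, n = 10), with 5 pairs above and 5 below 0 (exact permutation p = 0.494).

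**Figure D1:**
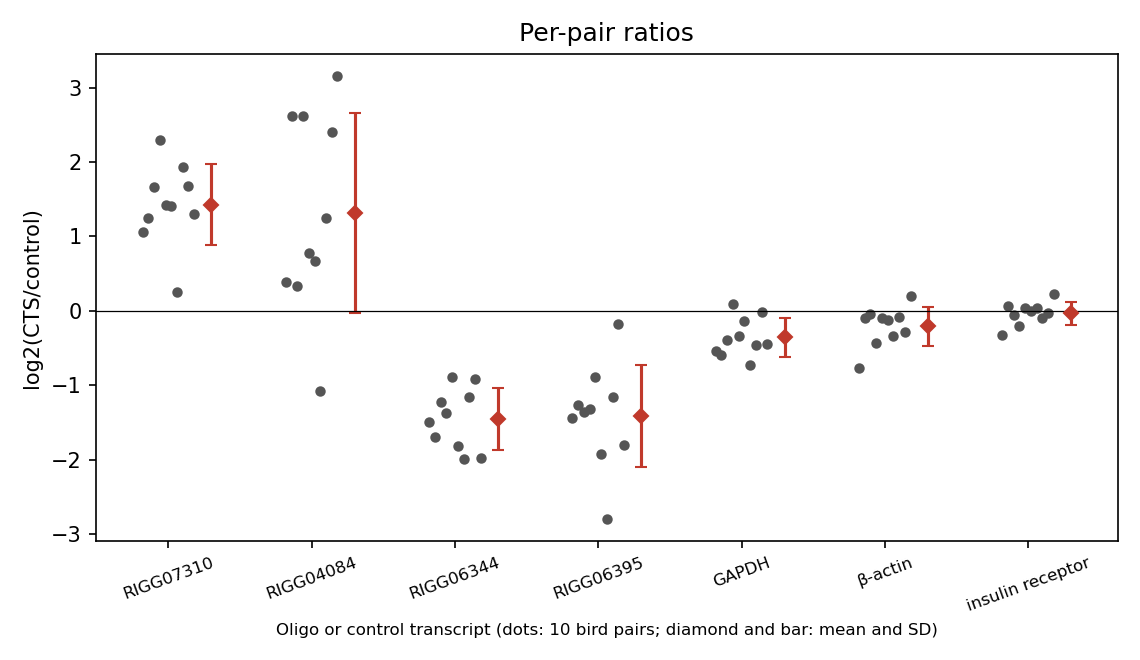
Log2 ratio of CTS over control for 4 oligos and 3 control transcripts. Each dot is 1 of the 10 bird pairs (mean of 2 dye-swapped arrays), and the diamond with its bar is the mean with its SD. All RIGG06344 pairs lie between -1.99 and -0.88, and GAPDH lies below 0 in 9 of 10 pairs.

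The called oligos were mainly bright ones. Of the 776, 651 belonged to the brightest 25% of oligos, where 12.7% were called, and 2 to the dimmest 25%, where 0.0391% were. Among 4308 oligos detected on at least 10 of 20 arrays in both conditions, 556 were called. None of the 1181 blank spots and none of the 218 spots of the repeated control oligo was called by limma when each kind was tested alone, and an unadjusted p under 0.05 was found for 63 and 13 of them. Of the 63 blank spots, 53 were higher and 10 lower in CTS, and of the 13 spots of the repeated oligo 10 were higher and 3 lower. The mean log2 ratio of all blank spots was 0.03 ± 0.04 (SD, n = 10 pairs; exact permutation p = 0.0469), above 0 in 6 of 10 pairs. With all spots tested together, 1 blank spot was called.

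Oligos called in 9 pairs mostly had the same sign in the pair left out. When each pair in turn was set against oligos called in the other 9, those higher in the others averaged 0.37 ± 0.12 (SD, n = 10 pairs) in the pair left out and those lower averaged -0.37 ± 0.13 (SD, n = 10). The share of these oligos with the same sign in the left-out pair was 89.3% ± 6.42 (SD, n = 10), and it was lowest in pair 10, at 73.8%.

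CTS and control were also compared within each scan day. On scan day 1 (12 arrays), 290 oligos were higher and 325 lower in CTS, and on scan day 2 (8 arrays) 148 were higher and 189 lower. These counts are from a fit on single arrays with a dye term and the pair as a block, at a within-pair correlation of 0.13 for all oligos. On all 20 arrays that fit gave 573 higher and 785 lower. The median log2 ratio of the 776 changed oligos, each taken in its direction over all arrays, was 0.38 on day 1 and 0.24 on day 2. Log ratios of all oligos spread less on day 2, with an SD per array of 0.13 to 0.25 against 0.31 to 0.54 on day 1. The smaller ratio on day 2 therefore need not be a weaker difference between CTS and control. No oligo had a CTS ratio that differed between days in limma (754 at an unadjusted p under 0.05). RIGG07310 was at 1.53 and 1.36 on days 1 and 2, RIGG04084 at 1.83 and 0.66, RIGG06344 at -1.60 and -1.15, and RIGG06395 at -1.44 and -1.20. The limma adjusted p of RIGG04084 on day 2 was 0.177. GAPDH was at -0.34 ± 0.09 (SE) and -0.33 ± 0.07 (SE), β-actin at -0.20 ± 0.10 (SE) and -0.18 ± 0.06 (SE), and the insulin receptor at -0.05 ± 0.07 (SE) and -0.01 ± 0.04 (SE). With scan day as a covariate of the dye effect, on all 20 arrays with the pair as a block, 557 oligos were higher and 705 lower.

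The counts depended on the values, the model and the centring. Plain background subtraction gave 189 oligos higher and 208 lower, mean pixel intensities 177 and 235, and the authors' processed values 104 and 136. Of the 397, 412 and 240 oligos called there, in this order, 383, 400 and 229 were among the 776 in the same direction. Only 49.4%, 51.5% and 29.5% of the 776 were thus called again, so the list of oligos changed with the values and not only its size. With all 20 arrays, a dye term and the pair as a random block, 573 oligos were higher and 785 lower, and 767 of the 776 oligos were among them. Of the 776 oligos, 46.0% were higher, and with arrays centred on their median without loess 28.3% of 823 called oligos were higher.

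A dye effect was called for 7232 oligos (35.3%), of which 3850 were brighter in Cy5 and 3382 in Cy3, with a median size of 0.20 on the log2 scale. Of the 776 oligos changed in CTS, 363 (46.8%) also had a dye effect. Log ratios spread less on scan day 2, so in pairs scanned on both days a dye effect may cancel only in part. With a dye effect that could differ between days, on all 20 arrays, 760 of the 776 were still called, against 767 without that term. In limma, 1 oligo had a dye effect that differed between days. With loess within each block of spots in place of loess over the whole array, 3709 oligos had a dye effect. The 7232 therefore include effects that depend on how ratios were centred across the array. How far the dye effect follows the place of a spot on the array was not tested. The 35.3% may therefore not be bias of the oligos themselves. RIGG07310 averaged 0.91 ± 0.54 (SD, n = 10 arrays) with CTS in Cy5 and 1.94 ± 0.60 (SD, n = 10) with CTS in Cy3. RIGG06395 averaged -1.83 ± 0.76 (SD, n = 10) and -0.99 ± 0.62 (SD, n = 10). RIGG04084 averaged 1.03 and 1.59, and RIGG06344 -1.66 and -1.25. GAPDH lay at -0.52 ± 0.09 (SE, n = 10) with CTS in Cy5 and at -0.19 ± 0.07 (SE, n = 10) with CTS in Cy3, where its adjusted p in the exact permutation test was 0.0527. The insulin receptor spots took opposite signs in the 2 orientations, 0.13 with CTS in Cy5 and -0.20 with CTS in Cy3, where the adjusted p in the exact permutation test was 0.00586 although the spots were not well above background. From 1 orientation alone, 4164 oligos were called with CTS in Cy5 and 4589 with CTS in Cy3, which count dye effects as CTS effects.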

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

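The tests of spots near background and of each scan day alone were chosen after the data were seen. Pair 10 stood apart in how far it shared the changes of the other pairs. Of the oligos called in the other 9 pairs, 73.8% had the same sign in pair 10, against 87.0% to 98.3% in the other pairs. Dixon's test was run on 22 groups of 10 values, of which about 1.1 would pass its limit by chance, and this was the only one that did. Spots of the repeated control oligo, which were left out of the counts of oligos, were detected above background in 5.23% of readings in Cy3, against 0.779% of blank spots.

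For the 776 oligos changed in CTS, chance was weighed by turning the sign of random pairs. Only 1 of 100 assignments gave as many called oligos, the real one, the smallest share this test can give. The highest of the others gave 2, which argues against chance as the source of the count. The test does not bear on single oligos. Noise of spots near background is argued against by detection: 71.6% of the called oligos were detected on at least 10 of 20 arrays in both conditions. A difference between scan days as the whole source is argued against by the 615 oligos called on day 1 alone, of which 99.2% had the same sign on day 2, although 6 pairs contributed an array to each day. Food withdrawal, handling, transport and the way of killing remain open as biological sources and were not tested, because they differ together between the conditions.

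For the 7232 oligos with a dye effect, dye labels were exchanged within random pairs. Only 1 of 30 assignments gave as many oligos, the real one, the smallest share this test can give. The highest of the others, which exchanged the labels of 1 pair, gave 5352. Chance as the source of the count is argued against, and a source in the place of spots on the array was not tested.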

How the results depend on the processing

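Of 31 alternatives, 4 (mean pixel intensity, each scan day alone, and the set without pairs 3, 8 and 10) were chosen after seeing the data. The counts of oligos higher and lower in CTS stayed within 1.5 times of 357 and 419 in 19 alternatives each, and the cause of the other changes was not tested unless given. In both tallies the 19 include the 10 sets with 1 pair left out and Aquantile after loess. Among the other alternatives, more counts moved than stayed. Plain background subtraction gave 189 higher and 208 lower, the authors' processed values 104 and 136, mean pixel intensity 177 and 235, median centring 233 higher, and ordinary least squares 256 lower. A fold of at least 1.5 left 48 and 52, and 63 oligos with a dye effect, by construction. The pair as a replicate block on 20 arrays gave 573 and 785, no replicate block 682 and 900, and scan day as a covariate 557 and 705. The fit without a block counted the 2 arrays of the same extracts as separate replicates. The replicate block used 1 within-pair correlation of 0.13 for all oligos, so it treated these arrays as nearly independent. Arrays with CTS in Cy5 alone gave 1884 and 2280 and those with CTS in Cy3 alone 2269 and 2320, in which dye bias does not cancel. Scan day 2 alone gave 148 and 189, with 4072 dye effects, and scan day 1 alone 4429 dye effects, both from fewer arrays and, for CTS, in the model with the pair as a block. The set without pairs 3, 8 and 10 gave 195 and 230. Loess within blocks gave 3709 dye effects. With each pair left out in turn, 248 to 356 oligos were higher, 292 to 469 lower, and 6303 to 7026 had a dye effect. Aquantile after loess cannot change these ratios. RIGG07310, RIGG06344 and RIGG06395 kept direction and call in all 31 alternatives. Aquantile and the fold of at least 1.5 could not have changed that, as these IDs were picked for large ratios. Neither RIGG04084, GAPDH nor β-actin reversed in those run for them. Of the 776 called oligos, 1 was called in the opposite direction with CTS in Cy5 alone and 6 with CTS in Cy3 alone. The alternatives on gene lists were not run, for want of gene names. Signal over background limits the dim oligos: the median oligo of the dimmest array lay 6 units above background in Cy5.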

Other observations

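The comparison between pairs, the tests of chance pairing, single slides and shared scan day, and the runs with mean pixel intensity and without pairs 3, 8 and 10 were chosen after the data were seen. The spread between pairs exceeded that between dye-swapped arrays for 563 oligos (F test on 9 and 9 degrees of freedom, adjusted p under 0.05). This sets different birds against repeats of the same extracts, so the count describes the arrays and shows no effect. The first component of the pair deviations over the brightest 25% of oligos held 35.4% of their variance, with loadings of 0.80 for pair 8, -0.48 for pair 10 and 0.26 for pair 3 and between -0.16 and -0.04 for the rest. The count was 17 without pairs 3, 8 and 10, 226 with mean pixel intensity and 2 with median centring in place of loess. It was 216 without pair 8, 272 without pair 10, and 357, 316, 370, 347 and 374 without pairs 3, 4, 7, 9 and 12.

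Of 100 pairings of the arrays, 1 gave as many oligos, the real one, and the highest of the others gave 1, which decides nothing because the real pairing joins repeats of the same extracts. Artifacts of single slides as the whole source are argued against by the mean r of 0.47 between the 2 arrays of a pair over the brightest 25% of oligos, against -0.05 between different pairs (permutation p = 1e-05 over 10 pairs, the smallest the permutations can give). A scan day shared by both arrays is argued against as the whole source by the 6 pairs scanned on different days. Their mean r was 0.56, from 0.40 to 0.78. In pairs 2, 4, 5 and 12, each scanned on 1 day, r was lower, at 0.31, 0.37, 0.32 and 0.32. Log ratios spread less on day 2, so a dye effect may cancel only in part in those 6 pairs and enter r. That was not tested, and a part of scan day in r stays open. The amount of labelled RNA in an extract stays open: the loading and the brightness of the CTS over the control channel had a Pearson r of 0.30 (permutation p = 0.441) and a Spearman rho of 0.02 (permutation p = 0.973) over 10 pairs, and r was 0.42 (permutation p = 0.327) without the 2 pairs farthest in brightness, the only such relation computed. No biological explanation was tested.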
